A study of Homo sapiens with 18 samples.

How the data were processed

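RNA sequencing of 18 libraries of polyadenylated RNA was analysed, 3 from each of the 6 melanoma cell lines A375, G-361, SK-MEL-1, RPMI-7951, SK-MEL-3 and SH-4. The cell line and the type (primary or metastatic) were taken from the labels, and libraries were named by the number in their title. The titles and table columns of RPMI-7951, SK-MEL-1 and SK-MEL-3 carry a catalogue code in place of the line's name, so that these columns were matched by title and the line was taken from the cell line label of that sample. The deposited values are TPM, length-normalised transcript abundances scaled to a fixed total, per gene and library, computed by the authors. Per the submitters' processing notes HISAT2 and StringTie were used with the genome build hg38; their versions, settings and annotation are not given in the sources used here. Each library sums to 1000000 TPM, so the table keeps no sequencing depth, and neither counting intervals nor detection limits can be given. TPM are shares of a total: a few abundant transcripts, such as the mitochondrial ones, lower the values of all other genes where they take more of it. An exact 0 can be a failed estimate, because genes that most cells use were also listed at 0 in single lines, and such genes are given here as listed at 0. No fold is given for a gene listed at 0 in the line named or, between types, in any line.

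The table has 58288 genes, of which 57980 identifiers matched GENCODE release 29 (GRCh38) without their version number. Coordinates and gene types come from that release, 1-based. In 253 cases a symbol stood on several identifiers, and 60.9% of the values were 0. Genes with at least 1 TPM in at least 3 libraries were kept (18761 genes, 14074 of them protein coding) and log2(TPM + 1) was used, on which scale fold changes of weakly expressed genes are understated. No pair of libraries was identical.

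Lines were compared in a linear model of the 18 libraries with limma 3.58.1 in R 4.3.3 (with the data.table package, version 1.17.8), with a mean-dependent prior variance (trend), an F test over the 6 lines and a contrast of each line with the mean of the other 5. P-values were adjusted by Benjamini and Hochberg, and a gene was called in a line at an adjusted p under 0.05 and a log2 difference of at least 1. Because each line is set against the mean of the other 5, a gene far higher in 1 line tends to give negative differences in the rest. Types were compared with limma on the 6 line means, 3 against 3, as metastatic minus primary, at an adjusted p under 0.05. The 27 fixed gene lists (462 entries; 5 genes found under older symbols, 1 not found) were tested with limma's camera, two-sided, with a preset correlation between genes of 0.01 and again with an estimated correlation, adjusted over the 27 lists between types and over the 162 tests of a list in a line. The lists were pigment cell differentiation, neural crest, undifferentiated state, YAP and TEAD targets, mesenchymal markers, epithelial adhesion, collagen and matrix, matrix proteolysis, MAPK output, proliferation, p53 targets, melanoma drivers and 9p21, interferon response, MHC class I, MHC class II, cancer-testis antigens, chemokines and NF-kB, oxidative phosphorylation, glycolysis and hypoxia, cholesterol synthesis, metastasis suppressors, metastasis-associated genes, heat shock and ER stress, and markers of fibroblasts, immune cells, endothelial cells and keratinocytes. Some genes stand in more than 1 list. For a list in a line, the estimated correlation came from differences between libraries of a line. It does not allow for genes that vary together across lines. Between types it came from differences between lines of a type. Distances between lines were compared by an exact permutation test over the 10 splits of the lines.

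The samples, tests, lists, alternatives and the rule for named genes were fixed before the data were examined. Between types, called genes were to be named, filled up to 10 per direction by the smallest p among genes whose types did not overlap and that differed by at least 1 on the log2 scale. For each line, the 4 called genes with the widest gap above the next line and the 2 with the widest gap below were named, and for each list up to 4 members with the widest span of line means. Further members of the lists could be named with their line means. Named genes were protein coding, and some that the rule names are not reported here. Alternatives were other pseudocounts, filters, scalings and models, and leaving out each library or line. Rescaling without mitochondrial genes, and other scalings for the lists in each line, were added after the data had been seen.

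The models were tested on 20 simulated data sets with the real gene means and spreads, 18761 genes and 200 changed genes. For SH-4 against the other lines, 96.2% of the changes of 1.5 and 99.9% of the changes of 3 on the log2 scale were called, with 1.15 false calls on average. For metastatic against primary lines, 52.1% of the changes of 3 and 87.7% of the changes of 6 were called, with 7.35 false calls on average. In the simulation for SH-4 the lines had equal means apart from the changed genes, and in both simulations genes varied independently. The real data differ in both respects, so these rates describe the models under the simulated settings only. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15 with pandas 2.3.3.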

Results

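The transcriptomes of 6 established human melanoma cell lines were compared, each from 3 libraries of polyadenylated RNA. The labels class A375, G-361 and SK-MEL-1 as primary and RPMI-7951, SK-MEL-3 and SH-4 as metastatic, and the series presents the lines as a data resource for metastatic and primary melanoma. SK-MEL-1 is generally described as derived from a lymphatic metastasis, so that each comparison of types rests on its label as primary. Expression was given in TPM, transcript abundance scaled to a fixed total, so that each library summed to 1000000 and sequencing depth is unknown. A library listed between 20145 (SH-4) and 23783 (G-361) genes above 0. Mitochondrial transcripts took 10.5% ± 0.93 (SD, n = 3) of the TPM in A375, 13.7% ± 0.20 in RPMI-7951, 22.2% ± 2.80 in SH-4, 22.3% ± 0.88 in G-361, 23.2% ± 0.52 in SK-MEL-1 and 31.3% ± 0.53 in SK-MEL-3. Gene values below are mean TPM ± SD of the 3 libraries of a line unless stated otherwise. Nothing in the labels says that these libraries came from separate cultures, so p-values between lines measure only the spread between libraries, which may be technical.

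The first question was how far the 6 lines differ from each other. The lines separated into those with a strong pigment cell programme and those without it, and RPMI-7951 stood apart by its matrix genes. Of 18761 genes tested, 17618 (93.9%) differed among the lines at an adjusted p under 0.05 (limma F test), and the line means of 14687 of these spanned at least 1 on the log2 scale. Correlations of log2(TPM + 1) between libraries ranged from 0.987 to 0.990 within a line and from 0.790 to 0.896 between lines. G-361 and SK-MEL-3 had the most similar means (r = 0.901, across genes, which are not independent replicates), and SK-MEL-1 and RPMI-7951 the least similar (r = 0.797). Relative to the mean of the other 5 lines, 2682 genes were higher and 1604 lower in RPMI-7951, 2621 and 1604 in A375, 2376 and 2248 in SK-MEL-1, 1987 and 1222 in G-361, 1294 and 2045 in SH-4, and 1166 and 2216 in SK-MEL-3. The balance in A375 and SK-MEL-3 depended on the scaling: after median-ratio scaling it was 1955 higher and 1919 lower in A375 and 1610 higher and 1746 lower in SK-MEL-3, and the median difference over all genes went from 0.12 to -0.04 in A375 and from -0.24 to -0.07 in SK-MEL-3. Without the mitochondrial genes, a choice made after seeing the data, the median difference in RPMI-7951 went from 0.07 to -0.06. With a pseudocount of 0.1 in place of 1, the counts of lower genes reached 2719 in A375, 2231 in G-361, 3745 in SK-MEL-1, 2868 in RPMI-7951, 3818 in SK-MEL-3 and 3913 in SH-4, and those of higher genes reached 3113 in G-361 and 1909 in SK-MEL-3.

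**Figure D1:**
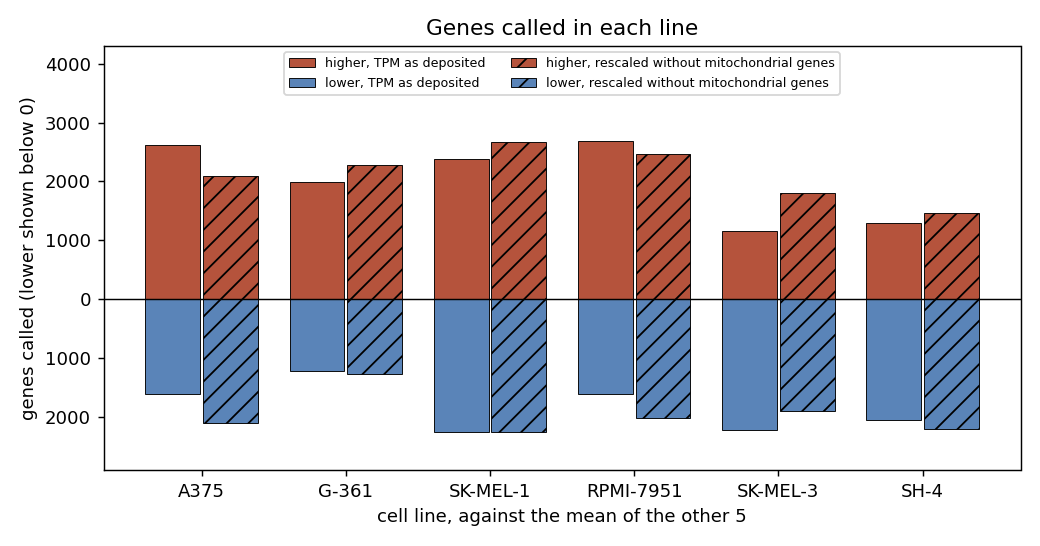
Number of genes called higher (above 0) and lower (below 0) in each line against the mean of the other 5, at an adjusted p under 0.05 and a log2 difference of at least 1. Plain bars use TPM as deposited and hatched bars TPM rescaled without the mitochondrial genes, where the calls in SK-MEL-3 went from 1166 higher and 2216 lower to 1799 and 1887.

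Pigment cell genes were low in A375 and RPMI-7951 and high in the other 4 lines. Of 19 measured members of the pigment cell differentiation list, 18 were lower and none higher in A375, and 18 were lower and 1 higher in RPMI-7951. In G-361 16 were higher and none lower, in SK-MEL-1 14 and 4, in SK-MEL-3 13 and 1, and in SH-4 12 and 2; the same numbers passed when adjusted over the list alone. The list passed the set test in all 6 lines, also with an estimated correlation (adjusted p from 0.000943 in A375 to 0.0317 in SK-MEL-1). Taken between libraries of a line, that correlation was 0.0163, against 0.676 taken between lines of a type. The set test in a line therefore does not allow for genes that vary together across lines. PMEL, the structural protein of melanosome fibrils, reached 7802 ± 1080 in G-361, 4117 ± 753 in SK-MEL-3, 2500 ± 247 in SH-4 and 1050 ± 112 in SK-MEL-1, against 1.62 ± 0.54 in A375 and 1.47 ± 0.68 in RPMI-7951. TYR, which encodes tyrosinase, the rate-limiting enzyme of melanin synthesis, was 751.1 ± 64.8 in SH-4 and was listed at 0 in all 3 libraries of A375. The pigmented lines differed in their melanogenic enzymes: TYRP1 was 2010 ± 31.3 in G-361 but was listed at 0 in SK-MEL-1, and DCT was 1389 ± 284 in SK-MEL-3 but 4.25 ± 0.40 in SK-MEL-1. MITF, the transcription factor that drives this programme, ranged from 8.03 ± 2.01 in RPMI-7951 and 45.8 ± 4.91 in A375 to 375.9 ± 7.82 in G-361. SOX10, a neural crest factor, was 40.3 ± 4.74 in RPMI-7951 and 698.4 ± 6.30 in A375. In the neural crest list of 17 genes, 9 were higher and 2 lower in A375, and the list passed in no line (smallest adjusted p = 0.133, A375). With median-ratio scaling 8 were higher and 4 lower in A375 (adjusted p = 0.0540), and without the mitochondrial genes 9 and 4 (0.0395, past the threshold). Within it L1CAM was 463.4 ± 28.2 in G-361, TFAP2B 175.1 ± 3.95 in A375, RXRG 92.3 ± 6.0 in A375 and TMEM158 276.5 ± 19.2 in RPMI-7951.

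**Figure D2:**
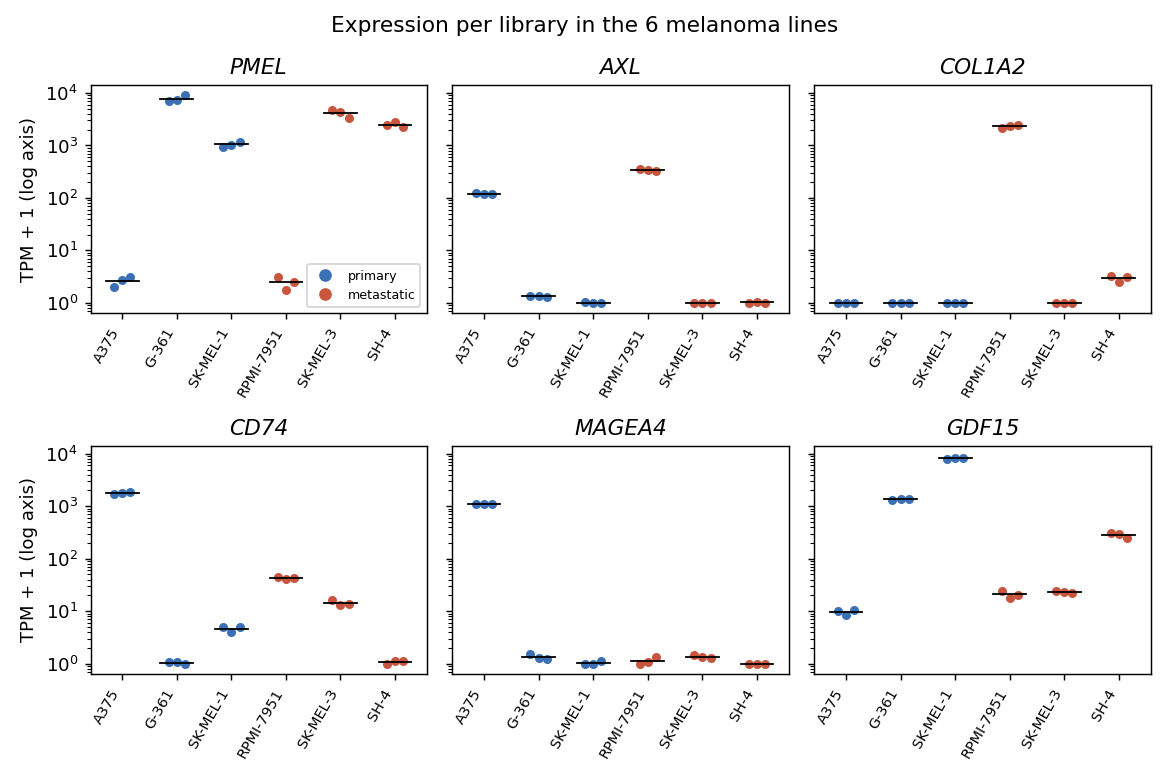
TPM + 1 on a log axis for 6 genes in the 18 libraries, with a point for each library, a bar at the mean of 3 and the colour giving the labelled type. PMEL means ran from 1.47 TPM in RPMI-7951 to 7802 in G-361, and COL1A2 was high in RPMI-7951 (2337).

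Genes of the undifferentiated melanoma state were high in RPMI-7951 and, to a lesser level, in A375. Of 18 measured members, 14 were higher in RPMI-7951 and none lower, and in A375 11 were higher and 2 lower (adjusted p with an estimated correlation 0.00106 and 0.0317). AXL, a receptor tyrosine kinase, was 338.3 ± 11.2 in RPMI-7951 and 120.1 ± 3.46 in A375, and lay at or below 0.33 in the other 4 lines. NT5E (334.2 ± 8.71), LOXL2 (334.1 ± 24.5) and WNT5A (219.0 ± 0.51) were likewise highest in RPMI-7951. The list was lower in G-361 and SH-4, where 9 and 11 members were lower and 0 and 1 higher (adjusted p = 0.00218 and 0.0143 with an estimated correlation), and in SK-MEL-1, where 9 were lower and 2 higher (adjusted p = 0.0283, and 0.0757 with an estimated correlation). Among 14 YAP and TEAD targets, 9 were higher and none lower in RPMI-7951 (adjusted p = 0.0213 with an estimated correlation), and 6 were lower and 1 higher in G-361 (0.0371). In SK-MEL-1 7 were lower and 1 higher (adjusted p = 0.0287, and 0.0952 with an estimated correlation). Among them in RPMI-7951 were CYR61 at 395.2 ± 21.9, CTGF at 306.2 ± 16.1 and CRIM1 at 91.0 ± 5.08. Of 12 mesenchymal markers, 9 were higher and none lower in RPMI-7951 (adjusted p = 0.0124 with an estimated correlation), with FN1, fibronectin, at 4634 ± 131, S100A4 at 1197 ± 107 and TWIST2 at 127 ± 1.68. In G-361, SH-4 and SK-MEL-3, 6, 7 and 9 were lower and 0, 1 and 1 higher (adjusted p = 0.00595, 0.0345 and 0.0256, and 0.0505, 0.105 and 0.0938 with an estimated correlation). S100A4 was also 686.8 ± 28.9 in A375 and at most 1.77 in the other 4 lines, and PRRX1 was highest in SK-MEL-1, at 248.2 ± 13.2. Of 13 genes of epithelial adhesion, 6 were higher and 1 lower in G-361 (adjusted p = 0.0404, and 0.333 with an estimated correlation), a call lost with median-ratio scaling (0.0722). CDH1, E-cadherin, was 91.2 ± 8.89 in SK-MEL-1 and 36.7 ± 9.22 in G-361 and at most 0.36 elsewhere. KRT18 was 154 ± 2.56 in A375, CDH3 94.9 ± 7.23 in SK-MEL-1 and CLDN1 81.6 ± 1.07 in SK-MEL-3.

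Matrix genes set RPMI-7951 apart. Of 21 collagen and matrix genes, 18 were higher in RPMI-7951 and none lower (adjusted p = 0.00461 with an estimated correlation), and 17 were lower in SK-MEL-1 and none higher (0.0149). In G-361, SH-4 and SK-MEL-3, 9, 10 and 11 were lower and 3, 1 and 1 higher (adjusted p = 0.0176, 0.00128 and 0.0256, and 0.186, 0.0860 and 0.211 with an estimated correlation). The median log2 difference of this list was 4.89 in RPMI-7951 and 1.10 in A375, against -0.88 in G-361, -0.94 in SH-4 and -1.21 in SK-MEL-3. Since RPMI-7951 is part of the mean that other lines are set against, their lower calls are not separate from its high levels. COL1A2, a chain of type I collagen (chromosome 7, 94394561 to 94431232, GRCh38), was 2337 ± 125 in RPMI-7951, 1.95 ± 0.39 in SH-4 and was listed at 0 in the other 4 lines. Its partner chain COL1A1 was 1261 ± 52.4 in RPMI-7951 and at most 2.80 elsewhere, a log2 difference of 9.35 (SE 0.13, adjusted p = 1.87e-17). THBS1 was 1391 ± 106 and COL5A1 467.0 ± 20.4 in RPMI-7951. Of 19 genes of matrix proteolysis, 14 were higher in RPMI-7951 and none lower, or 2 lower with median-ratio scaling or without the mitochondrial genes (adjusted p = 0.0487 with an estimated correlation), with the gelatinase gene MMP2 at 2390 ± 271, the urokinase gene PLAU at 300.7 ± 13.2 and its receptor PLAUR at 223.0 ± 7.74. The 6 measured fibroblast markers were all higher in RPMI-7951 (adjusted p = 0.0292 with an estimated correlation), led by THY1 (323.2 ± 38.2), FAP (246.8 ± 23.1) and COL3A1 (107.3 ± 12), while LUM was 76.5 ± 5.14 in RPMI-7951 and 65.4 ± 9.83 in G-361. COL3A1, LUM and DCN also stand in the collagen and matrix list, so this call is not separate from that one. Expression over a whole culture cannot tell melanoma cells that express these markers from fibroblasts among them. In A375 4 and in SK-MEL-1 5 of the fibroblast markers were lower and none higher (adjusted p = 0.00497 and 0.00840, and 0.0866 and 0.103 with an estimated correlation). These lower calls, too, are not separate from the high levels in RPMI-7951. The lists of immune, endothelial and keratinocyte markers, with 4, 3 and 3 measured members, passed in no line. PTPRC, the pan-leukocyte marker, did not exceed 0.35 in any library and the endothelial cadherin CDH5 did not exceed 0.51. LCP1, which also occurs in tumour cells, was 210.7 ± 14.6 in RPMI-7951 and 124.2 ± 1.53 in SK-MEL-1, and TP63 was 45.3 ± 13.3 in RPMI-7951.

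Immune-related genes differed by line. All 11 measured genes of the MHC class II list were higher in A375 (adjusted p = 0.00461 with an estimated correlation), with CD74 at 1794 ± 58.5, HLA-DRA at 790.2 ± 16.8, HLA-DRB1 at 251.2 ± 4.04 and HLA-DPA1 at 229.8 ± 23.0. In G-361, 9 of these genes were lower and in SK-MEL-1 7, and none was higher (0.0149 and 0.0252). A375 is part of the mean that these lines are set against, so their lower calls are not separate from its high levels. Of 24 interferon response genes, 13 were higher in SK-MEL-3 and none lower, and 10 were higher in RPMI-7951 and none lower; both passed with the preset correlation (adjusted p = 5.76e-11 and 0.0140), and with an estimated correlation the adjusted p was 0.0546 and 0.482. In A375, G-361 and SH-4, 5, 7 and 10 were lower and 1 was higher in each (adjusted p = 0.000925, 0.0335 and 0.0280, and 0.310, 0.525 and 0.515 with an estimated correlation). With median-ratio scaling 10 and without the mitochondrial genes 12 were lower in A375, and with either 2 were lower in RPMI-7951. OAS2 (114.3 ± 17.8), MX1 (102.1 ± 20.3) and XAF1 (39.3 ± 8.91) were highest in SK-MEL-3, whereas MX2 was highest in RPMI-7951 (134.6 ± 1.26). Of 15 MHC class I genes, 6 were higher and none lower in RPMI-7951 (adjusted p = 0.00108, and 0.167 with an estimated correlation), among them HLA-B at 574.0 ± 38.6 and ERAP2 at 122.3 ± 16.4. Cancer-testis antigens, which are normally expressed in germ cells, were high in A375, where 11 of 18 measured members were higher and 1 lower (adjusted p = 0.0117, and 0.0717 with an estimated correlation), and in G-361, where 9 were higher and 2 lower (0.0368, and 0.112 with an estimated correlation). Cancer-testis antigens were low in SK-MEL-3 and SH-4, where 13 and 11 were lower and 0 and 2 higher (0.00564 and 0.0355 with an estimated correlation). MAGEA4 was 1112 ± 18.2 in A375 and at most 0.36 elsewhere, PAGE5 was 364.3 ± 25.2 in A375, and PRAME ranged from 0.02 ± 0.03 in SK-MEL-3 to 573.5 ± 54.9 in G-361. HLA and MAGE genes have near-identical copies, so that their values are uncertain. Of 19 chemokine and NF-kB genes, 10 were lower and 1 higher in SH-4 (adjusted p = 0.0160, and 0.0976 with an estimated correlation). CCL2 was 114.5 ± 17.9 in RPMI-7951 and CXCL1 was 116.2 ± 18.8 in SK-MEL-3.

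Of 23 proliferation genes, 16 were lower in SK-MEL-1 and 7 in G-361, and none was higher in either (adjusted p = 0.01 in both with an estimated correlation). In RPMI-7951 9 and in SH-4 4 were higher and none lower (0.0140 and 0.0122). In A375 5 were higher and none lower (adjusted p = 0.00256, and 0.0860 with an estimated correlation), but 2 were higher with median-ratio scaling or without the mitochondrial genes, and without the latter 5 were higher in RPMI-7951. CDC20, an activator of the anaphase-promoting complex, was 21.2 ± 1.91 in SK-MEL-1 and 323.8 ± 7.98 in RPMI-7951, and CCNA2 was 16.4 ± 1.96 and 139.2 ± 9.60. Of 20 p53 targets, 12 were higher and 2 lower in SK-MEL-1 and 10 were lower and 2 higher in RPMI-7951 (adjusted p = 0.000145 and 0.00045), and with an estimated correlation the adjusted p was 0.0863 and 0.105. In G-361 7 were higher and 1 lower, and in SH-4 5 were lower and 1 higher (adjusted p = 0.00107 and 0.00408, and 0.132 and 0.186 with an estimated correlation). GDF15, a stress-induced cytokine, reached 8181 ± 278 in SK-MEL-1, against 8.68 ± 1.14 in A375, and the cell cycle inhibitor CDKN1A was 733.3 ± 96.0 in SK-MEL-1 and 29.7 ± 3.14 in RPMI-7951. MAPK output genes, which report signalling through ERK, were higher in SK-MEL-1 (11 of 19, 1 lower) and lower in SK-MEL-3 (11 of 19, 1 higher), with an adjusted p of 0.0252 and 0.0230 with an estimated correlation. LIF was 328.3 ± 18 in SK-MEL-1 and 6.53 ± 0.87 in SK-MEL-3, and EPHA2 was 214.4 ± 5.63 and 8.05 ± 0.29. Cholesterol synthesis genes were higher in SH-4 (12 of 20, 1 lower) and lower in A375 (11 of 20, 1 higher), but only with the preset correlation (adjusted p = 5.32e-08 and 0.000151, against 0.105 and 0.268 with an estimated correlation). SQLE was 297.3 ± 48.8 in SH-4 and 37.5 ± 1.88 in A375. In the oxidative phosphorylation list 1 of 24 genes was lower and none higher in RPMI-7951 (adjusted p = 0.00108, and 0.0860 with an estimated correlation), and PPARGC1A, a regulator of mitochondrial biogenesis, ranged from 0.56 ± 0.11 in A375 to 63.1 ± 8.61 in SK-MEL-1. The lists of glycolysis and hypoxia, of heat shock and ER stress, of metastasis suppressors and of metastasis-associated genes passed in no line. Their widest spans were those of ADM (0.84 ± 0.25 in SK-MEL-3, 75.5 ± 11.6 in SK-MEL-1), DDIT3 (556.8 ± 96.2 in SK-MEL-1, 21.5 ± 5.34 in SH-4), CADM1 (0.07 ± 0.08 in SH-4, 100.1 ± 38.5 in SK-MEL-3) and GDF15. Of the melanoma drivers and 9p21 genes, 7 of 19 were higher and 1 lower in SK-MEL-1 (adjusted p = 0.00840, and 0.0677 with an estimated correlation). CDKN2A and its neighbour MTAP were listed at 0 in all 3 libraries of SH-4, against means of 1.81 to 285.8 and of 14.7 to 111.7 in the other lines. Of the 162 tests of a list in a line, 57 passed with the preset and 28 with the estimated correlation. That estimate was taken between libraries of a line.

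Each line also had genes that were almost its own. In A375, FDCSP was 210.4 ± 11.1 and was listed at 0 in the other 5 lines, GTSF1 was 186.5 ± 13.7 and MEOX2 161.5 ± 4.74. MBP was listed at 0 in all 3 libraries of A375, and MLPH, which carries melanosomes on actin, was 4.06 ± 0.91 there against at least 142.8 elsewhere, a log2 difference of -5.70 (SE 0.11, adjusted p = 6.77e-16). In G-361, MAGEB2 was 116.8 ± 1.92, PENK 71.0 ± 1.40, PDE4C 53.1 ± 3.68 and PASD1 47.6 ± 3.49, each below 1 in the other lines, and FAM20C and SERPINH1 were 0.48 ± 0.10 and 0.45 ± 0.42, against at least 21.9 and 17.9 elsewhere. In SK-MEL-1, FMOD, fibromodulin, was 543.8 ± 6.62, SLC9A3 407.4 ± 26.8, CPXM1 290.9 ± 2.25 and FRG2 257.2 ± 4.04, of which FRG2 belongs to a family of near-identical copies and is uncertain. COL4A2 was 0.54 ± 0.33 in SK-MEL-1 against at least 88.7 elsewhere (log2 difference -7.05, SE 0.08, adjusted p = 3.74e-18), and SNRPN, an imprinted gene that overlaps SNURF and is uncertain, was listed at 0 in its 3 libraries. In RPMI-7951, TMEM119 was 494.8 ± 44.8 and APCDD1L 455.7 ± 6.47, each below 0.1 elsewhere, and ATAD1 (0.01 ± 0.01) and PLPP2 (0.31 ± 0.21) were lower than in every other line. In SK-MEL-3, the homeobox gene HOXB13 was 191.9 ± 17.1 and at most 11.7 elsewhere (log2 difference 4.84, SE 0.07, adjusted p = 4.15e-17). CCL18 (30.4 ± 0.08) and HMX1 (22.1 ± 2.25) lay below 1 in the other lines. PRKAR1A, the regulatory subunit of protein kinase A (chromosome 17, 68511780 to 68551319, GRCh38), was listed at 0 in all 3 libraries of SK-MEL-3 and was at least 235.5 in the other lines, and CTHRC1 was 0.10 ± 0.12 against at least 119.6. In SH-4, WFDC1 was 521.1 ± 42.4, SUCNR1 97.2 ± 7.93, PLN 81.2 ± 6.53 and TAC4 29.1 ± 2.20. DYNLT3 was listed at 0 in its 3 libraries, and CD9, a tetraspanin, was 2.59 ± 0.92 against at least 164.5 elsewhere.

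The second question was whether metastatic lines differ from primary lines, with the line as the unit and 3 lines against 3. The gene with the smallest p was DSG2, a desmosomal cadherin (chromosome 18, 31498043 to 31549008), with line means of 116.1 in G-361, 51.1 in SK-MEL-1 and 39.0 in A375, against 0.18 in RPMI-7951 and 0 listed in SK-MEL-3 and SH-4. It did not pass (adjusted p = 0.163, higher in 3 of 3 primary lines). EGR3, an immediate early transcription factor, was 26.0 to 37.1 in the primary and 1.29 to 2.44 in the metastatic lines (log2 difference -3.56, SE 0.42, adjusted p = 0.490). PCDHGA12, a clustered protocadherin, was 0.04 to 2.36 in the primary and 31.4 to 39.6 in the metastatic lines (4.28, SE 0.54, adjusted p = 0.523), and it shares exons with other protocadherins of its cluster, so that its value is uncertain. BST2, an interferon-induced membrane protein, was 0.72 to 3.62 and 32.3 to 149.2 (4.42, SE 0.68, adjusted p = 0.688). No gene passed in either direction with limma on the line means: 0 were higher and 0 lower at an adjusted p under 0.05. The same held without SK-MEL-1, but fewer lines then remained, so this cannot show whether its label matters. At an unadjusted p under 0.05, 151 were higher and 393 lower in metastatic lines, 2.90% of the genes. The 3 lines of each type did not overlap for 419 genes higher and 991 lower in metastatic lines, 7.52% of the genes, where 10% arise by chance. Treating the 18 libraries as independent gave 618 higher and 1324 lower genes, and with the line as a random block there were 3 and 14, BST2, DSG2 and EGR3 among them. The random block used a shared correlation for all genes and the degrees of freedom of 18 libraries, although the type varies only between lines. Its calls therefore do not replace the test on the line means.

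The other genes with the smallest p among those whose types did not overlap did not pass either. Higher in all 3 metastatic lines, with log2 differences from 1.45 to 2.82, were C1S, ID2, ILDR2, IDH2, ABHD12, APOBEC3B and IFIT3, and also, with no fold given, SLC18A1, which was listed at 0 in G-361 and SK-MEL-1. C1S, a protease of the complement system, was 7.61 to 18 against 0.57 to 0.85, and IDH2, the mitochondrial isocitrate dehydrogenase, was 49.9 to 91.2 against 23.0 to 29.8. Lower in all 3 metastatic lines, with log2 differences from -2.70 to -2.49, were C21orf33, KDR and PRSS12. COCH, LRCH2, KIAA1324L and TBC1D30 were also lower in all 3, the first being listed at 0 in SK-MEL-3 and SH-4, LRCH2 and KIAA1324L in SH-4 and TBC1D30 in RPMI-7951, and no fold is given for them. NKX2-5, a cardiac homeobox factor also among these genes, was 6.91 to 34.6 in the primary lines and was listed at 0 in the metastatic lines, so that no fold is given. KDR, the VEGF receptor, was 4.75 to 7.34 against 0.02 to 0.39.

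Of the 27 fixed gene lists, 12 passed between types with a preset correlation and 0 with an estimated correlation. Without SK-MEL-1, 9 passed with the preset correlation. All 23 proliferation genes had a higher mean in metastatic lines (median log2 difference 0.82, adjusted p = 5.95e-12, and 0.404 with an estimated correlation), but the 3 lines of each type separated for 4 of them. CDC20 was 272.0 ± 3.43 in the primary line A375, above SK-MEL-3 (100.9 ± 3.77) and SH-4 (144.7 ± 15.9). Higher in metastatic lines were also 19 of 24 interferon response genes (0.91, 1.93e-08), 13 of 15 MHC class I genes (0.53, 1.61e-06) and 17 of 20 cholesterol synthesis genes (0.61, 1.87e-06), given as median log2 difference and adjusted p. With an estimated correlation their adjusted p was 0.404, 0.404 and 0.431. Lower were 18 of 20 p53 targets (-0.89, 1.61e-06), 14 of 18 cancer-testis antigens (-1.74, 0.000173) and 10 of 13 genes of epithelial adhesion (-0.49, 0.0335), each with an adjusted p of 0.404 with an estimated correlation. Collagen and matrix genes (16 of 21 higher, adjusted p = 0.000903), YAP and TEAD targets (12 of 14, 0.0029), matrix proteolysis (13 of 19, 0.0029), fibroblast markers (6 of 6, 0.0029) and the undifferentiated state (13 of 18, 0.0450) passed as higher in metastatic lines. With an estimated correlation these had an adjusted p of 0.614, 0.455, 0.404, 0.454 and 0.766. All 5 were lost without the line RPMI-7951, where the adjusted p was 0.852, 0.219, 0.655, 0.873 and 0.334 and the direction turned for collagen and matrix and for the undifferentiated state.

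No list had a member that passed over all genes, and adjusted over the list alone 1 member passed in each of 2 lists, CHAC1 among heat shock and ER stress genes (adjusted p = 0.0386) and KDR among endothelial markers (0.00115). The undifferentiated state was also lost without the line G-361 or SK-MEL-1 (adjusted p = 0.627 and 0.149). With a pseudocount of 0.1, no filter, a filter at 5 TPM, median-ratio scaling, no mitochondrial genes or 18 independent libraries its adjusted p lay between 0.0615 and 0.103. It lay between 0.0503 and 0.0619 when any of these single libraries was left out: A375 1, G-361 1 or 2, RPMI-7951 1, 2 or 3, SK-MEL-1 1, 2 or 3, or SH-4 3. Epithelial adhesion was lost without G-361, SK-MEL-1, SK-MEL-3 or SH-4 (0.154, 0.151, 0.075 and 0.0538), with no filter (0.0885) or with 18 independent libraries (0.0723), collagen and matrix without SK-MEL-1 (0.151), the fibroblast markers without A375 (0.0524) or with no filter (0.0675) and cholesterol synthesis without SH-4 (0.0549). The other 15 lists did not pass, from endothelial markers and MAPK output (adjusted p = 0.0734 each) and melanoma drivers (0.0749) to immune markers (0.845). Pigment cell differentiation (0.560), neural crest (0.584), mesenchymal markers (0.748), MHC class II (0.741), oxidative phosphorylation (0.372), glycolysis and hypoxia (0.845), heat shock and ER stress (0.379) and keratinocyte markers (0.654) were among them. So were chemokines and NF-kB (0.310), metastasis-associated genes (0.321) and metastasis suppressors (0.845). In these the test pointed up, whereas the median log2 difference was -0.25 and the mean 0.22 for chemokines and NF-kB, 0.13 and -0.06 for metastasis-associated genes, and -0.15 and -0.0051 for metastasis suppressors.

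**Figure D3:**
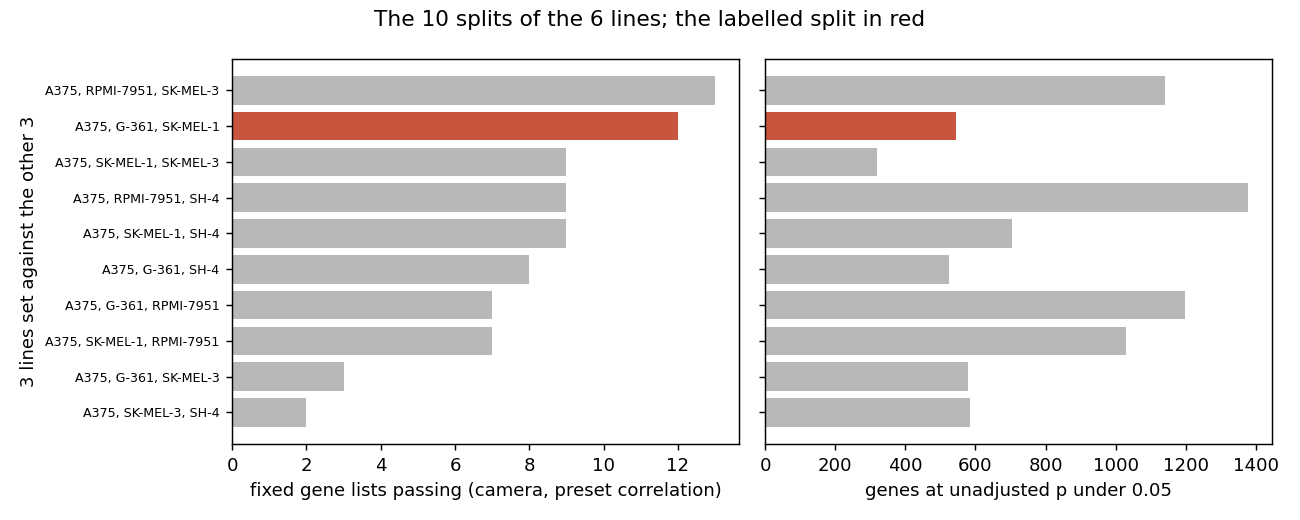
Fixed gene lists passing with the preset correlation (left) and genes at an unadjusted p under 0.05 (right) for the 10 ways to set 3 of the 6 lines against the other 3, with the labelled types in red. The labelled split gave 12 lists and 544 genes, and the other 9 gave 2 to 13 lists and 318 to 1378 genes.

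Lines of the same type were not closer to each other than lines of different type. The mean distance (1 minus Pearson r of log2 line means) was 0.143 between types and 0.154 within a type, a difference of -0.0102 (one-sided exact permutation test over 10 splits, p = 0.9, where the smallest p the design allows is 0.1). Of the variance of a gene, the median share between types was 9.50%, that between lines of a type 78.3% and that between libraries of a line 4.95%. The other 9 splits of the lines gave 8.85% to 15.1% in place of 9.50%, so this share is not particular to the labelled types.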

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

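Rescaling without mitochondrial genes, and other scalings for lists in single lines, were chosen after seeing the data. Of 20 results that answer a comparison, 9 kept their direction and stayed within 1.5 times under every alternative, and 36 of 68 named genes and lists did not change their call. These 36 were the genes that the rule named for single lines. Every gene and list named between types changed its call under at least 1 alternative. For the genes this arose only in fits on the 18 libraries, and no gene passed between types on the line means under any alternative. Leaving out each library in turn left the count of genes differing among lines at 17101 to 17489, the lists passing between types at 11 to 12 and the genes passing between types at 0 and 0; without each line in turn the last were again 0 and the lists 9 to 14. With a pseudocount of 0.1, lower genes numbered 2719 (A375), 2231 (G-361), 3745 (SK-MEL-1), 2868 (RPMI-7951), 3818 (SK-MEL-3) and 3913 (SH-4), and higher genes 3113 (G-361) and 1909 (SK-MEL-3); a smaller pseudocount widens differences of weakly expressed genes by construction. Without mitochondrial genes, higher genes in SK-MEL-3 numbered 1799. Between types, 18 libraries taken as independent gave 618 higher and 1324 lower genes, which by construction counts libraries as lines. The line as a random block gave 3 and 14. That fit used a shared correlation for all genes and the degrees of freedom of 18 libraries, and which of these gave the calls was not tested. An estimated correlation left 0 lists. Without RPMI-7951 the direction turned for collagen and matrix (adjusted p = 0.852) and for the undifferentiated state (0.334); RPMI-7951 carried the highest levels of both. Without each line in turn the adjusted p ranged from 6.31e-06 to 0.852 and from 9.17e-05 to 0.627. The difference of distances stayed between -0.0853 and -0.0101 under every alternative, and the shares of variance moved by less than 1.5 times. Of the 57 calls of a list in a line, 0 turned and 1 was lost under the other scalings, and 7 other tests passed under 1 or both of them. Some counts of members moved by over 1.5 times: most are given with the list, and a count of 1 became 0 or 2 for oxidative phosphorylation and pigment genes in RPMI-7951, melanoma drivers in SK-MEL-1, and YAP and TEAD targets and epithelial adhesion in G-361. Since depth is unknown, it cannot be said which weakly expressed genes were within reach of each library.

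The replicate numbers did not pair the libraries. Deviations from the line mean of libraries with the same number had a mean correlation of 0.00095 (from -0.0408 to 0.0533 over 45 pairs), and 7 of 18 libraries correlated best with their own number. With the replicate number as a block, 17587 genes differed among lines, A375 had 2619 higher and 1604 lower genes, and no count of a line's calls moved by 1.5 times; between types, the block on 18 independent libraries gave 410 and 910.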

Other observations

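The tests of neighbouring genes and the splits of the lines by type were chosen after the values had been seen, and the rescaling without mitochondrial genes was added then. Genes listed near 0 in a single line were sought among protein-coding genes: 89 lay below 0.1 TPM in 1 line and at 5 TPM or more in each of the other 5. Such a value can be a failed estimate, so it does not show that a transcript was absent. SH-4 had 30 of these genes, SK-MEL-3 26, SK-MEL-1 14, A375 10, RPMI-7951 7 and G-361 2. The genes named here were chosen after their values were seen. In SH-4 they included MTAP, GLUL, which encodes glutamine synthetase, IGFBP3 and PDLIM1. In SK-MEL-3 they included the purine enzyme PNP, the dNTP hydrolase SAMHD1 and SERPINB1. In A375 they included GPR143, a melanosomal receptor, and in SK-MEL-1 the receptor TLR4 and the adhesion molecule NCAM1.

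Some of these genes were neighbours. In the order of 14052 protein-coding genes along the chromosomes, 4 pairs of neighbours that do not overlap were near 0 in the same line, a restriction made after a first count that included overlapping genes, where 10000 random placements of the same number of genes gave at most 3 (permutation p = 0.0001, the smallest they can give). Of the 4, 3 came from 1 run in SK-MEL-3, with overlapping genes among them, so that estimates that failed gene by gene stay open. In SK-MEL-3, AMZ2, ARSG, SLC16A6, WIPI1 and PRKAR1A were listed at 0 in all 3 libraries over 303.7 kb of 17q24.2 (chromosome 17, 68247574 to 68551319, GRCh38), next to KPNA2 at 421.5 TPM; some of these genes overlap, and their split of reads is uncertain. The 4 other annotated genes that overlap this segment, 3 of which reached 1 TPM or more in another line, had a highest value of 0 in SK-MEL-3. They overlap genes of the run, with MIR635 lying inside WIPI1, so that their values are not independent of it. Loss of the DNA segment may be the cause in SK-MEL-3, but these genes add little to that. In SK-MEL-1 loss stays open: none of the 8 other genes (highest 0) around the neighbours EML1 and EVL reached 1 TPM in another line. Around the overlapping SNRPN and SNURF, the highest of 5 others was 0.292 TPM, above the limit of 0.1, for RPL5P1, a processed pseudogene whose reads may come from its parent gene, and SNHG14, the one other that reached 1 TPM in another line (71.9), was at most 0.0118. DNA was not measured, and silencing was not tested.

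More genes were lower than higher in SK-MEL-3 (65.5% of its calls) and SH-4 (61.2%). In SK-MEL-3 the lower share was 51.2% without the mitochondrial genes (50.6% to 52.9% without each library), a fall large enough for its larger mitochondrial share to be the cause. This rescaling moves all other genes alike and can only lower the share in this line, so any other shift of all genes stays open. The lower share was 70.0% among genes with a mean of at least 20 TPM, so the excess was not confined to weakly expressed genes. This share used TPM as deposited, where a shift of all genes keeps it high whatever the depth. Whether weakly expressed genes were also lost in SK-MEL-3 stays open. In SH-4 the lower share was 60.1% without the mitochondrial genes (59.6% to 61.5%), too close to the limit of 60% set beforehand to decide. It was 47.3% among genes of at least 20 TPM (45.3% to 48.9%), as a lower depth that loses weakly expressed genes would give. Fewer expressed genes in SH-4 itself would give the same and stay open, since depth is unknown.

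Regroupings of the libraries could hardly have come out otherwise. Correlations were 0.987 to 0.990 within a line and 0.790 to 0.896 between lines, so mixing lines widens the spread within a group. The regroupings therefore show only that libraries of a line resemble each other. Since libraries of a line may be repeats of 1 culture, the regroupings do not bear on differences between cultures. Of 100 regroupings of the 18 libraries into 6 groups of 3, the real one included, 1 gave as many genes differing among lines, the real one, with 17618 against at most 1638 in the others. The same held for the higher and lower genes of each line, with 1 of 100 in all 12 counts; the highest other counts of higher and lower genes were 686 and 793 (A375), 652 and 733 (G-361), 1937 and 714 (SK-MEL-1), 4 and 39 (RPMI-7951), 4 and 45 (SK-MEL-3) and 543 and 727 (SH-4). For types, the 10 splits of the 6 lines are too few for a share under 0.05. The real split gave 0 higher and 0 lower genes, which every split reaches by construction, and the highest other counts were 3 and 2. The lists passing numbered 12 in the real split and at most 13 in the others, 2 of 10 splits reaching 12. The 4 splits with RPMI-7951 and A375 on the same side gave 1029 to 1378 genes at an unadjusted p under 0.05 against 544 in the real one, which points to a structure of the lines other than their labelled type.

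B2M, a component of MHC class I, varied between libraries of 1 line, from 94.9 to 713.1 TPM in G-361 and from 99.5 to 528.9 in A375. Of 9741 values of a protein-coding gene in a line with a mean of at least 100 TPM and no library at 0, 48 had a highest library at least 3 times the lowest. B2M was not the widest of these. By ratio, the widest were TOMM6 in SH-4 (2.01 to 387.1 TPM), AP002990.1 in G-361 (7.70 to 543.2) and HNRNPH2 in SK-MEL-1 (2.26 to 153.5).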
